A study of Homo sapiens with 9 samples.

How the data were processed

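The series lists 9 samples of a HEK293T clone without RNASEH2A, all treated with a control siRNA or an siRNA against TOP1. Of these, 4 are RNA-seq libraries (2 siNC and 2 siTOP1) and 5 (2 siNC and 3 siTOP1) have the library source "other"; no values of those 5 were at hand, and they were not analysed here. Per the labels' protocols, RNA was isolated on columns with DNase treatment and libraries were made from poly(A)-selected RNA with a directional kit. HISAT2 and featureCounts and the build GRCh38 are named in the submitters' processing notes, without versions or settings, so how reads that map to several places were counted is not given in the sources used here.

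The authors deposited 1 table of TPM values for 20048 genes, with Ensembl identifiers, coordinates, strand and a length column. Each library's TPM values sum to 1000000. Columns were assigned to samples by matching their names with the sample titles, and 6 further columns of per-sample values matched no sample and were not used. The 4 columns were not identical to one another. Symbols came from a table of gene identifiers and symbols, which matched 20024 of the 20048; the other 24 lie on unplaced contigs and are listed at 0 in all 4 libraries. All 13 mitochondrially encoded genes are listed at 0 as well, so nothing is said of them. The length column equals the whole span from gene start to gene end in the 19174 rows with 1 interval, and the union of intervals in the other 874. It is not the length behind the TPM values, since with it at most 4.97% of values came out as whole reads. Instead, the values of the 17271 genes above 0 in any library were found to be whole multiples of a common step per gene and library in 100% of genes (tolerance 0.001 reads). From these steps, whole reads and an exonic length per gene were recovered, giving 9285463 and 8470886 reads in siNC replicates 1 and 2 and 9226374 and 10320745 in siTOP1 replicates 1 and 2. A gene's recovered reads are the smallest whole numbers that fit, and a common factor over the 4 libraries cannot be excluded. On a transcript of 1 kb, 1 read was worth 0.466 to 0.574 TPM. The 10 genes with the highest values held 2.78% to 3.31% of all TPM in a library.

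Replicates were compared before they were averaged. Genes with at least 20 recovered reads summed over the 2 replicates of a group were used, which were 13083 genes for siNC. The chi-square per gene was 2.03 between the siNC and 1.98 between the siTOP1 replicates. Both lie above the value of 1 for sampling noise, so the replicates were counted as separate libraries. TPM values were tested as log2(TPM + 1) in limma 3.58.1 (R 4.3.3) with eBayes and trend=TRUE, on the 4 RNA-seq libraries with group as the only term, without a count model. Genes with a TPM of at least 1 in at least 2 of the 4 libraries were tested (13849), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and means and SDs are of TPM over 2 libraries.

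Gene lists (24) were fixed before the data were examined, together with the tests, the samples in them and the rule for named genes. Each list was set against all other tested genes with camera at a preset correlation of 0.01, adjusted over the 21 lists with at least 5 tested members, and again with an estimated correlation. Of the 9 lists called by camera, 0 held with an estimated correlation. The fry test, which does not compare a list with other genes, called 9 lists in 1 direction, 5 of them shared with camera, and 19 for change in either direction. Of the mitochondrially encoded genes 0 were tested. Named genes were TOP1, the RNase H2 subunits, the 12 largest rises and 12 largest falls in log2 fold change among called genes with a symbol, a mean of at least 5 TPM in a group and no overlap between groups, and up to 4 members per list with the smallest p; further list members named as not called, the remaining called members of the very long genes and the highest marker of another cell type were chosen after their values were seen. Some list members that the rule names are not reported here. Gene span is end minus start plus 1 from the deposited coordinates.

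The limma and camera steps were tested on simulated data for siTOP1 against siNC. Reads were drawn for the 13849 genes at the real means and depths with a negative binomial dispersion of 0.002, which matched the spread between real replicates, in 10 runs with 200 changed genes each. The fit recovered 11.0% of genes changed 1.25-fold, 60.0% at 1.5-fold, 82.8% at 2-fold and 92.4% at 4-fold, and 7.37% of calls fell on unchanged genes. A list of 30 genes shifted 1.2-fold was called in 10 of 10 runs and unchanged lists in 0 of 210 tests. Genes were drawn independently, so these runs do not show how camera behaves where genes of a list vary together. In the real data the estimated correlation of the called lists went from -0.0128 (S-phase genes) to 0.469 (ribosomal protein genes). The share of calls on unchanged genes holds for 200 changed genes per run, whereas 3582 genes were called in the real data.

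Alternatives were other pseudocounts (0.1 and 5), other filters, median-of-ratios scaling, quantile normalization, other variance models, the replicate number as a block, each library left out in turn and, added after the data were seen, voom weights on the recovered reads and removal of a trend with exonic length. GC content was not corrected because no genome sequence was used. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.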

Results

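Polyadenylated RNA was measured in HEK293T cells, a line derived from human embryonic kidney that carries the SV40 large T antigen. The cells belonged to a clone labelled T3-8 in which RNASEH2A, the gene of the catalytic subunit of RNase H2, had been knocked out. RNase H2 removes single ribonucleotides and RNA-DNA hybrids from DNA. Cells were given a negative control siRNA (siNC) or an siRNA against TOP1 (siTOP1), the gene of DNA topoisomerase I, which relaxes supercoiled DNA. The labels give the dosing as 5 + 5 pmol, and each group held 2 RNA-seq libraries (n = 2). Between 15967 and 16121 genes had a TPM (transcript abundance scaled by length to a total of 1000000) above 0 in each library, and the values traced back to between 8470886 and 10320745 whole reads per library. Replicates correlated across 13849 tested genes at Pearson's r = 0.993 for siNC and 0.994 for siTOP1, and libraries of different groups at 0.983. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

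The siTOP1 libraries were compared with the siNC libraries to find which transcripts changed when TOP1 was lowered in cells without RNase H2. TOP1 (ENSG00000198900, chromosome 20, 41028822 to 41124487, GRCh38) was measured first, as the siRNA's target. It stood at 66.6 and 62.8 TPM in the siNC libraries and at 10.6 and 10.7 TPM in the siTOP1 libraries. The mean fell from 64.7 ± 2.68 to 10.6 ± 0.0679 TPM (SD, n = 2), a 5.65-fold fall (log2 fold change -2.50, SE 0.0871, limma adjusted p = 7.53e-07). These values rested on 1283 and 1109 reads against 203 and 232. RNASEH2A (ENSG00000104889, chromosome 19, 12806584 to 12813640) was low in every library, at 3.58 and 2.23 TPM in siNC and 3.34 and 5.21 TPM in siTOP1, from 8 to 23 reads. Its values overlapped between groups (adjusted p = 0.237). The other subunits of RNase H2 did not pass the test either, with RNASEH2B at 5.06 ± 0.281 against 4.31 ± 0.139 TPM (adjusted p = 0.431) and RNASEH2C at 112.1 ± 6.82 against 105.5 ± 0.788 TPM (adjusted p = 0.368).

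The largest falls besides TOP1 included transcription factors of the immediate early class, which cells switch on within minutes of a stimulus. FOSB fell 8.47-fold, from 189.1 ± 2.84 to 21.5 ± 1.33 TPM (log2 fold change -3.08, SE 0.0716, adjusted p = 6.89e-08), which was more than TOP1 itself. EGR1 fell 4.603-fold, from 525.9 ± 5.46 to 113.7 ± 9.74 TPM, and FOS 2.75-fold, from 283.3 ± 12.7 to 102.4 ± 0.111 TPM (adjusted p = 2.72e-07 and 1.79e-06). The largest rises included SLITRK1, CHGA, SCG3, CPLX1 and SYN1, genes known from neurons or secretory granules. SLITRK1, a neuronal transmembrane protein, rose 5.59-fold from 0.676 ± 0.032 to 8.40 ± 1.14 TPM (adjusted p = 7.73e-05), and the granule proteins CHGA and SCG3 rose 5.22-fold and 4.65-fold. CPLX1 and SYN1, which act at synaptic vesicles, rose 3.78-fold and 3.53-fold. Among abundant transcripts, ARL6IP1, an endoplasmic reticulum membrane protein, rose 4.72-fold from 143.2 ± 4.59 to 679.8 ± 14.4 TPM (adjusted p = 6.89e-08). PSAT1, an enzyme of serine synthesis, rose 3.51-fold from 114.4 ± 1.75 to 404.4 ± 5.74 TPM (adjusted p = 2.72e-07).

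In all, 3582 of the 13849 tested genes changed (limma, Benjamini-Hochberg adjusted p under 0.05), 2160 of them higher and 1422 lower after siTOP1. Of these, 206 changed at least 2-fold, 144 higher and 62 lower, and the median size of the change among called genes was 0.41 on the log2 scale. In 64.7% of tested genes both siTOP1 values lay beyond both siNC values, against 33.3% by chance. The other large rises by the fixed rule were DISP2 (4.30-fold), CCDC92B (3.91-fold), PGAM4 (3.78-fold), SGPP1, a sphingosine-1-phosphate phosphatase (3.57-fold), and SOWAHA (3.57-fold). PGAM4 is a close copy of PGAM1, and reads can be shared between them, so its value is uncertain. The other large falls were PRAC1 (4.53-fold), LYSMD2 (3.76-fold), RBM47 (2.65-fold), LDLRAD3 (2.59-fold), TSEN15, a subunit of the tRNA splicing endonuclease (2.51-fold), PLAGL2 (2.50-fold), ELOVL7, a fatty acid elongase (2.43-fold), and MOB1A (2.41-fold). PRAC1 rested on 4 reads in each siNC library and on 0 and 1 in the siTOP1 libraries. Adjusted p-values of these 13 genes ranged from 6.01e-06 to 0.00225.

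The split between higher and lower genes depended on scaling, at 60.3% higher with TPM as deposited, 50.9% after median-of-ratios scaling, 50.8% after quantile normalization and 44.2% after a trend with exonic length was removed. The count fell to 1945 genes (1306 higher, 639 lower) when the variance was not fitted as a trend on abundance, to 2395 (1349 higher) without siTOP1 replicate 1 and to 2348 (887 lower) without siTOP1 replicate 2. An exact permutation test of 2 against 2 libraries cannot give a two-sided p under 0.333. The design holds 1 TOP1 siRNA condition, so effects of lower TOP1 and other effects of that siRNA were not separated. All libraries came from 1 clone without RNASEH2A, so no change can be tied to the lack of RNase H2.

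**Figure D1:**
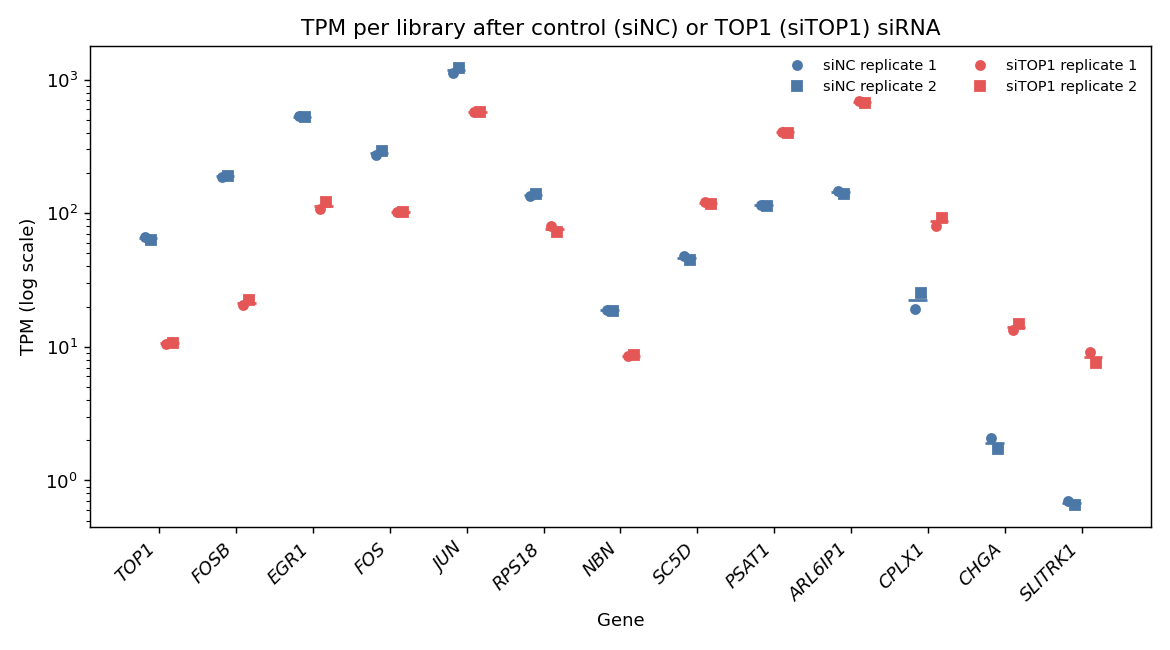
TPM (log axis) of 13 genes in each of the 4 libraries, with siNC in blue and siTOP1 in red, replicate 1 as circles, replicate 2 as squares and group means as lines. TOP1 fell from 64.7 to 10.6 TPM and FOSB from 189.1 to 21.5 TPM, while ARL6IP1 rose from 143.2 to 679.8 TPM.

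Of 21 tested immediate early genes 15 fell and 0 rose, also 15 when adjusted over the list alone, with a median log2 fold change of -0.49 (camera adjusted p = 3.12e-11; adjusted p = 0.244 with an estimated correlation). JUN, a partner of FOS in the AP-1 factor, fell 2.06-fold from 1177 ± 67.9 to 571.6 ± 3.13 TPM. The members that did not pass included NR4A1 at 17.2 ± 0.0481 against 17.1 ± 2.24 TPM and SRF at 168.9 ± 5.27 against 165.7 ± 9.57 TPM.

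Among cytosolic ribosomal protein genes, 19 of 30 fell and 0 rose (23 fell when adjusted over the list alone), with a median of -0.26 (camera adjusted p = 3.12e-11; adjusted p = 0.520 with an estimated correlation). RPS18 fell 1.79-fold from 137.5 ± 3.39 to 76.4 ± 5.00 TPM, RPL18 1.49-fold, RPLP2 1.47-fold, and RPL8, the most abundant of these 4, 1.35-fold from 2745 ± 116.2 to 2037 ± 113.4 TPM. Ribosomal protein genes have many processed pseudogenes, so their single values are uncertain. Genes of ribosome biogenesis and RNA polymerase I followed with 13 of 25 lower and 0 higher, also 13 when adjusted over the list alone (median -0.22, camera adjusted p = 2.26e-06; adjusted p = 0.244 with an estimated correlation). They included NOP56 (1.40-fold) and DKC1 (1.31-fold), core proteins of small nucleolar ribonucleoproteins, WDR12 (1.39-fold) and TAF1D (1.40-fold).

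Of 23 tested cholesterol synthesis genes 12 rose and 0 fell (14 rose when adjusted over the list alone), with a median of 0.29 (camera adjusted p = 6.07e-06; adjusted p = 0.244 with an estimated correlation). SC5D, a late enzyme of the pathway, rose 2.53-fold from 46.4 ± 1.97 to 118.7 ± 2.61 TPM. TM7SF2 rose 1.55-fold and MSMO1 1.51-fold.

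Among S-phase and replication genes 7 of 24 fell and 0 rose (9 fell when adjusted over the list alone), with a median of -0.11 (camera adjusted p = 9.99e-05; adjusted p = 0.244 with an estimated correlation). They included MCM4 and MCM7 of the replicative helicase (1.29-fold and 1.23-fold), the licensing factor CDT1 (1.29-fold) and TYMS (1.33-fold). In the list of ribonucleotide excision and RNA-DNA hybrid removal, 6 of 21 fell and 1 rose, the same counts as when adjusted over the list alone (median -0.12, camera adjusted p = 0.00272; adjusted p = 0.472 with an estimated correlation). The RNA helicases DDX5 and DDX39B fell 1.28-fold and 1.22-fold and the exonuclease EXO1 1.27-fold, while PCNA, the sliding clamp, rose 1.22-fold. Heat shock genes fell in 5 of 15 cases, with 0 higher (8 fell when adjusted over the list alone; median -0.15, camera adjusted p = 8.61e-04; adjusted p = 0.257 with an estimated correlation). HSPA1A and HSPA1B fell 1.31-fold and 1.28-fold, and because they are near-identical copies their separate values are uncertain. HSPH1 fell 1.18-fold.

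Condensin, cohesin and SMC5/6 genes fell in 4 of 24 cases with 0 higher, also 4 when adjusted over the list alone (median -0.09, camera adjusted p = 0.0174; adjusted p = 0.682 with an estimated correlation). The 4 were STAG2 (1.26-fold), NCAPH2 (1.19-fold), MAU2 (1.19-fold) and SMC4 (1.196-fold). This list call was lost without siNC replicate 1 (adjusted p = 0.179) and without siTOP1 replicate 2 (adjusted p = 0.124). Very long genes rose in 7 of 35 cases with 0 lower, also 7 when adjusted over the list alone, with a median of 0.16. Over all 13849 tested genes, 2160 were called higher and 1422 lower. The list had a camera adjusted p of 0.0328 (0.639 with an estimated correlation). The 7 were CNTNAP2 (2.00-fold), PTPRD (2.11-fold), ROBO1 (1.31-fold), TENM3 (1.42-fold), AUTS2, NRXN3 and ROBO2, and most of these are known for roles in neuronal adhesion or axon guidance. This call was lost without a filter on low values (adjusted p = 0.0642), after quantile normalization (0.174), without siNC replicate 2 (0.0777) and without siTOP1 replicate 1 (0.0855). Of the 9 lists called by camera, 4 did not pass the directional fry test: ribosomal protein genes (adjusted p = 0.0959), ribonucleotide excision (0.0806), condensin and cohesin (0.282) and very long genes (0.0633).

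**Figure D2:**
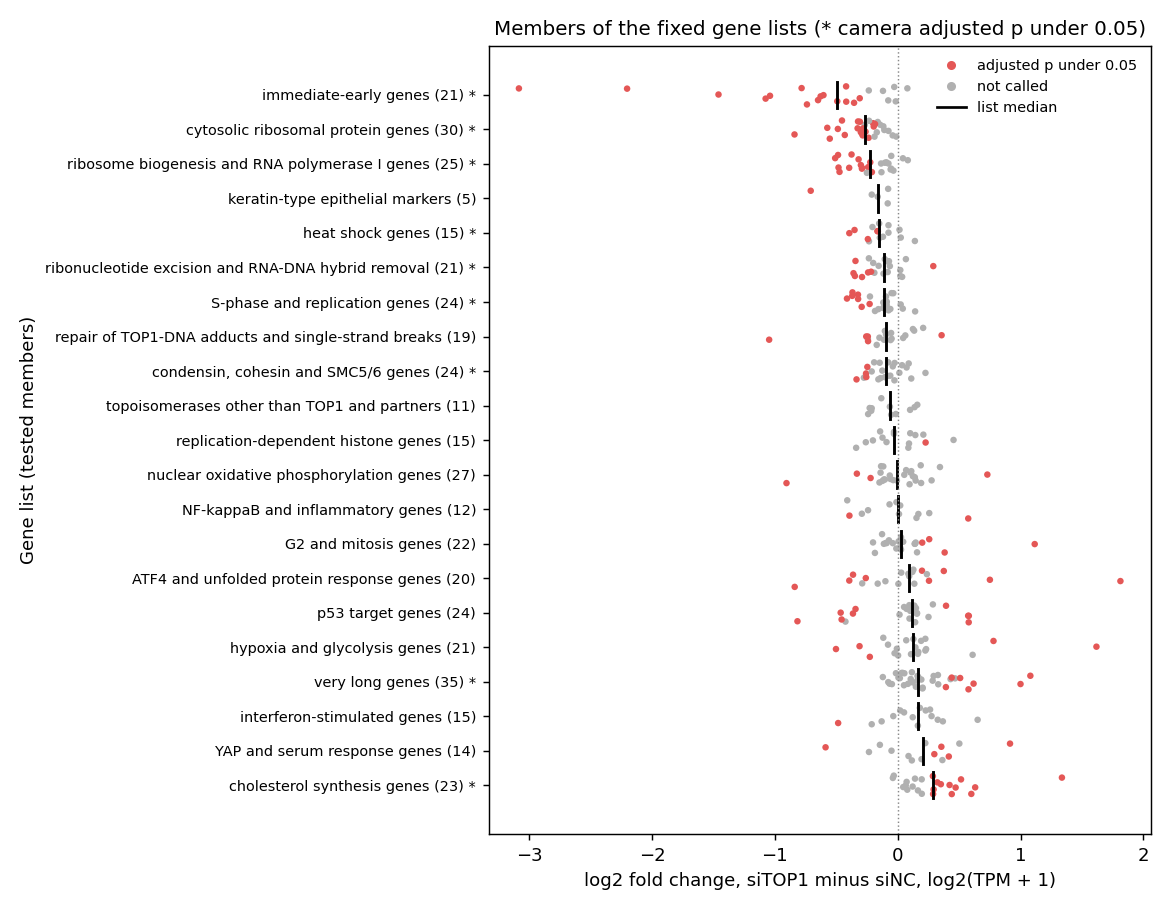
log2 fold change (siTOP1 minus siNC, on log2(TPM + 1)) of each tested member of the 21 gene lists, one list per line with its number of tested members, called members in red, others in grey and the list median as a black line. The immediate early genes lie farthest to the left, with a median of -0.49, and the cholesterol synthesis genes farthest to the right, with a median of 0.29.

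The other lists did not pass camera as groups, though 4 of them passed the directional fry test, which does not compare a list with other genes: hypoxia (adjusted p = 0.00452), ATF4 (0.0278), keratin-type markers (0.0278) and YAP genes (0.032). None of the 11 tested topoisomerases and partners other than TOP1 was called by limma, 0 also when adjusted over the list alone (camera adjusted p = 0.228). Of the members with the smallest p, 3 of 4 stood lower, TOPORS at 115.3 ± 1.07 against 99.7 ± 8.76 TPM (adjusted p = 0.0585), BLM at 63.8 ± 2.92 against 54.8 ± 2.46 TPM (adjusted p = 0.059) and RMI1 at 66.1 ± 7.39 against 55.8 ± 5.12 TPM (adjusted p = 0.0954). TOP2A stood at 330.3 ± 18.8 against 369.4 ± 30.2 TPM (adjusted p = 0.12). In the list of repair of TOP1-DNA adducts and single-strand breaks (camera adjusted p = 0.113), 4 of 19 fell and 1 rose, the same when adjusted over the list alone, and the list passed without siTOP1 replicate 1 (adjusted p = 0.0405). NBN, a subunit of the MRE11-RAD50-NBN complex, fell 2.07-fold from 18.8 ± 0.238 to 8.61 ± 0.0719 TPM and XRCC3 1.19-fold, while the ligase LIG3 rose 1.28-fold. TDP1, which removes TOP1 from DNA ends, stood at 23.6 ± 3.28 against 27.3 ± 0.242 TPM (adjusted p = 0.191).

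Among p53 target genes (camera adjusted p = 0.699), 4 of 24 rose and 5 fell (5 and 6 when adjusted over the list alone). BTG2 fell 1.76-fold, MDM2 1.38-fold and AEN 1.27-fold, TNFRSF10B rose 1.49-fold, and CDKN1A stood at 222.6 ± 12.8 against 244.9 ± 18.9 TPM (adjusted p = 0.181). Of the ATF4 and unfolded protein response genes (camera adjusted p = 0.632), 5 of 20 rose and 4 fell (5 each when adjusted over the list alone). PSAT1 and SDF2L1 rose, 3.51-fold and 1.30-fold, and the cystine transporter subunits SLC7A11 and SLC3A2 fell 1.79-fold and 1.29-fold. Hypoxia and glycolysis genes (camera adjusted p = 0.525) had 2 of 21 higher and 3 lower (5 and 3 when adjusted over the list alone), with SLC2A3, a glucose transporter, up 3.07-fold, BNIP3L up 1.72-fold, ADM down 1.42-fold and ENO1 down 1.17-fold. YAP and serum response genes (camera adjusted p = 0.264) had 4 of 14 higher and 1 lower (6 and 1 when adjusted over the list alone), with CRIM1 up 1.88-fold, LATS2 up 1.33-fold, TEAD1 up 1.28-fold and CCN1 down 1.502-fold.

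G2 and mitosis genes (camera adjusted p = 0.632) had 4 of 22 higher and 0 lower, also 4 when adjusted over the list alone, of which HMMR rose 2.17-fold, CENPE 1.30-fold, CCNB2 1.19-fold and BIRC5 1.15-fold. Nuclear oxidative phosphorylation genes (camera adjusted p = 0.525) had 1 of 27 higher and 3 lower (1 and 2 when adjusted over the list alone), with COX5A down 1.87-fold, COX5B down 1.26-fold, SDHD down 1.17-fold and ATP5PB up 1.66-fold. Interferon-stimulated genes (camera adjusted p = 0.538) had 0 of 15 higher and 1 lower in both counts, ISG15, at 60.6 ± 7.01 against 42.9 ± 1.35 TPM, a call lost with voom weights on recovered reads (adjusted p = 0.22) and without a variance trend (adjusted p = 0.0506). NF-kappaB and inflammatory genes (camera adjusted p = 0.525) had 1 of 12 higher, TRAF1 (1.49-fold), and 1 lower, NFKBIA (1.31-fold), also when adjusted over the list alone. The 15 tested histone genes did not pass as a group (camera adjusted p = 0.525), and most replication-dependent histone transcripts lack a poly(A) tail, which the libraries select for.

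Markers of epithelial, blood, fibroblast and endothelial cells were checked as well. Of 5 tested keratin-type epithelial markers CDH1 alone was called, 1.63-fold lower from 6.73 ± 0.0327 to 3.73 ± 0.247 TPM, also when adjusted over the list alone (camera adjusted p = 0.196). Of 15 T cell and blood cell markers 3 were expressed highly enough to be tested and of 13 fibroblast and endothelial markers 4, and none of these 7 was called. LCP1, the highest of them, stood at 68.1 ± 1.52 against 62.6 ± 4.40 TPM (adjusted p = 0.259).

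Because TOP1 acts on transcription of long genes, fold changes were set against the genomic span of each gene. Across 13849 genes, which are not independent replicates, Spearman's rho was 0.025, and the 4 single contrasts of 1 siTOP1 with 1 siNC library gave -0.04 to 0.092. The 2308 genes over 100 kb had a median log2 fold change of 0.08 against 0.03 in the others, with 381 higher and 152 lower, and a mean difference of 0.0455 that became 0.0196 after quantile normalization (camera p = 0.115; p = 0.615 with an estimated correlation). For the 880 genes over 200 kb the medians were 0.10 and 0.04, with 144 higher and 37 lower (camera p = 0.0437; p = 0.508 with an estimated correlation). Of the 149 genes over 500 kb, 23 rose and 0 fell, whereas of the 1666 genes up to 5 kb 296 rose and 201 fell.

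**Figure D3:**
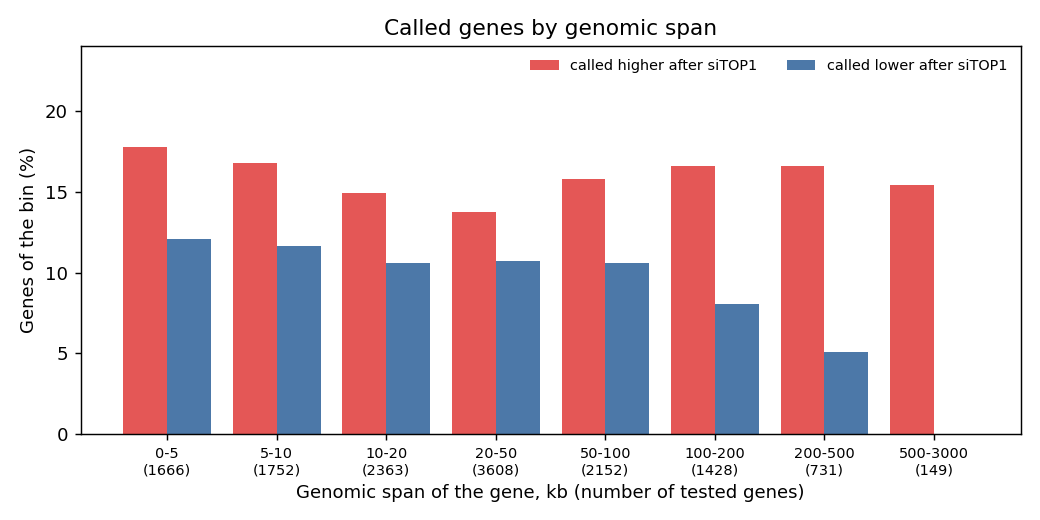
Percent of tested genes called higher (red) and lower (blue) after siTOP1 in bins of genomic span in kb, with the number of genes of each bin in brackets. The percent called higher lies between 13.7 and 17.8 in all bins, and the percent called lower goes from 12.1 in genes up to 5 kb to 0 in the 149 genes over 500 kb.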

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

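All alternatives were chosen before the data were examined except voom weights on recovered reads and removal of an exonic length trend, which were chosen after seeing the data. TOP1 was lower and past the threshold under all 15, with log2 fold changes from -2.60 (pseudocount 0.1) to -2.16 (pseudocount 5), and no gene called in the main fit was called in the opposite direction under any of them. Without a variance trend 1945 genes were called (1306 higher, 639 lower), 1760 of them among the 3582. Leaving out 1 library gave 2348 to 3099 genes, 1349 to 1956 higher and 887 to 1231 lower; the lone library was assumed to vary like the other group, the lowest count of higher genes came without siTOP1 replicate 1 and the lowest total without siTOP1 replicate 2. The 206 genes changed at least 2-fold became 57 with pseudocount 5, which shrinks folds by construction, 133 with a TPM of at least 5, where fewer genes are tested, and 335 with voom weights; the cause of the last was not tested. Of the 9 lists called, 0 held with an estimated correlation, and fry called 19 for change in either direction, another question. The other fits called 8 or 9 lists. The mean log2 fold change of genes over 100 kb exceeded that of the others by 0.0455 (camera p = 0.115 at the preset correlation), which passed the threshold after the exonic length trend was removed (0.0559, p = 0.0369) and for genes over 200 kb (0.0686, p = 0.0437), while quantile normalization lowered it to 0.0196 (p = 0.474) and over the other fits p ranged from 0.0598 to 0.336; the cause was not tested. The correlation of deviations between libraries of the same replicate number was 0.052, and 2 pairs are too few to show or exclude pairing. The fit with a replicate block called 4504 genes and 8 lists, without very long genes (camera adjusted p = 0.0514). Rescaling without mitochondrially encoded genes was not run, since these are listed at 0, nor was the GC correction.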

Other observations

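The tests of REST targets (the binomial test after their counts were seen), ERK feedback genes, 5'TOP messenger RNAs and matched lists, the gene family scan and the genes named here were chosen after the main results were seen. Beyond the fixed lists, genes were grouped by the letters that open their symbols, in 66 families of at least 20 tested members. RPL genes (large-subunit ribosomal proteins) had 33 of 49 lower and 2 higher, RPS genes (mostly small-subunit ribosomal proteins) 23 of 42 lower and 6 higher, DDX genes (RNA helicases) 13 of 31 lower and 0 higher, EIF genes (translation initiation factors) 15 of 54 lower and 2 higher, and TAF genes (mostly subunits around the TATA-binding protein) 8 of 28 lower and 2 higher. SMIM genes (small integral membrane proteins) had 8 of 25 higher and 0 lower. Their medians kept these directions after median-of-ratios scaling and quantile normalization. The adjusted camera p ranged from 2.63e-15 for RPL to 0.012 for SMIM, and with an estimated correlation it was 0.846 for each. No chromosome stood apart (23 tested, lowest camera adjusted p = 0.925).

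SCG3 and LYSMD2 are neighbours on chromosome 15, on opposite strands and pointing at each other, with 1984 bp between their ends. SCG3 rose from 3.12 ± 0.192 to 18.2 ± 1.82 TPM and LYSMD2 fell from 15.6 ± 1.37 to 3.41 ± 0.447 TPM (SD, n = 2). SLC2A3 was another transcript with a large rise, from 6.61 ± 0.279 to 22.4 ± 1.26 TPM. These are given as values; no explanation was tested.

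Some of the genes that rose are known from neurons or secretory granules, namely SYP, AP3B2, UNC13A, ACTL6B, KCNC1, SYN1, CHGA, SCG3, SLITRK1, DISP2 and CPLX1, a group picked by eye whose share among the large rises was not tested. All 11 were also called with voom weights on recovered reads, as were 3384 of the 3582 called genes. That is therefore no test of noise of genes with few reads. Among REST targets not seen before, the called genes were 17 higher and 0 lower (exact binomial test against the 60.3% higher among all called genes, one-sided p = 1.84e-04). This count does not decide on such noise, since the test was chosen after the count was seen and takes genes as independent. In addition, CHGB, SYT4, BDNF, RAB3C and OLFM1 had siNC means under 1 TPM and could hardly be called lower. These genes passed the TPM filter only through their siTOP1 values. They therefore also push the median and the camera result of this list, given below, towards a rise. Well-read genes were among the 17 as well, such as STMN3, from 66.9 ± 1.64 to 139.4 ± 5.30 TPM, and INA, from 106.7 ± 0.707 to 168.2 ± 5.42 TPM. Other well-read members of the list were not called. NEFM stood at 261.9 ± 15.7 against 266.9 ± 3.64 TPM (limma adjusted p = 0.759) and STX1A at 38.8 ± 2.70 against 34.5 ± 2.09 TPM (limma adjusted p = 0.206). A candidate explanation is weaker repression by REST, the repressor of neuronal genes, whose own transcript fell from 51.2 ± 1.30 to 36.1 ± 0.158 TPM (adjusted p = 0.00173): of 30 other genes known as REST targets, 17 rose and 0 fell (median 0.56, camera adjusted p = 3.49e-06 over the 4 added lists; 0.0926 with an estimated correlation). A wider neuronal programme in the siTOP1 cultures stays open as well, because of 22 neuronal genes not listed as REST targets 7 rose and 2 fell (median 0.22, camera adjusted p = 0.0121; 0.152 with an estimated correlation). The medians of these lists differed by 0.34, which a permutation test of list membership did not separate (two-sided p = 0.0897, 100000 resamples).

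Immediate early genes are short, so a trend with gene span or transcript length was weighed first. Of 10000 lists matched on span and mean TPM 0 percent had a median as low as -0.49 (lowest -0.20). For a trend with gene span, transcript length and abundance together, lists were matched on span, exonic length and mean TPM, and again 0 percent of 10000 had a median as low (lowest -0.26), which argues against such a trend. Lower output of the ERK pathway may contribute but was not decided by its feedback genes, of which 2 of 21 rose and 2 fell (median -0.0564, camera adjusted p = 0.2; 0.295 with an estimated correlation). An effect of lower TOP1 on these genes and a difference in handling or in the response to the siRNA cannot be separated by this design.

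Ribosomal protein genes are abundant and short, and a trend with abundance or transcript length was weighed for them: 0 percent of 10000 lists matched on mean TPM and exonic length had a median as low as -0.26 (lowest -0.17), which argues against it. The fall was shared by other messenger RNAs of the 5'TOP class, which carry the same start motif as ribosomal protein transcripts. Of 21 such genes 10 fell and 0 rose (median -0.18, camera adjusted p = 4.67e-07 over the 4 added lists; 0.0926 with an estimated correlation), among them EEF1A1, from 902.6 ± 25.2 to 581.2 ± 21.5 TPM. EEF2 and NPM1 had been seen lower before the test, and without them the median over 19 genes was -0.16 (camera p = 1.51e-06 at the preset correlation of 0.01 and 0.0347 at an estimated one, both unadjusted). This is consistent with a shift of the 5'TOP class as a whole, as a hypothesis found and tested on the same 4 libraries.

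The 4 libraries can be split into 2 and 2 in 3 ways. The real split called 3582 genes with limma and was the 1 split to call any, the highest of the others being 0. Each of the other splits puts siNC and siTOP1 libraries together in both groups. The difference between the siRNAs then adds to the spread within groups, so their lack of calls is no measure of what arises without a difference. Besides, 3 splits are too few for a share under 0.05.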
